A study of Tetrahymena thermophila with 4 samples.

How the data were processed

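The series examined N6-methyladenine (m6A) in the DNA of Tetrahymena thermophila strain SB210 during vegetative growth. Tetrahymena is a ciliate, a unicellular eukaryote that keeps a silent germline micronucleus and a polyploid, transcribed macronucleus in the same cell, and the labels place every library on the macronuclear genome. There were 4 libraries. The first was single-molecule real-time (SMRT) sequencing of genomic DNA on 8 SMRT cells, a method in which modified bases are read from the time the polymerase pauses at each base. The others were chromatin immunoprecipitation (ChIP-seq) of the histone variant H2A.Z with an anti-HA antibody, the input of that experiment, and sequencing of DNA protected from micrococcal nuclease (MNase-seq), which maps nucleosomes. The H2A.Z results below combine the ChIP and input libraries with nucleosomes and m6A calls from the other libraries. The labels do not say whether the input and MNase-seq libraries came from the same cells. Each assay had 1 library. There were therefore no replicates, no test across samples could be made, and no p-value is given.

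The deposited call lists give 1 line per adenine and strand, with a modification score on the Phred scale made by the PacBio kinetics caller. The other columns that the authors deposited with each call are the number of reads on that strand (coverage), the 41 bases around the adenine, the ratio of the inter-pulse duration to that predicted for unmodified DNA (IPD ratio), the estimated share of molecules carrying the modification with its interval, and an identification quality, also on the Phred scale. The full list held 525464 calls. The second list held 283759 calls, and these were the calls of the full list with an identification quality above 20, which was checked call by call. That second list, called the quality list here, was the main set. Reads of all 8 SMRT cells had been pooled by the authors, so differences between cells could not be measured. The files list only calls, so the depth at adenines without a call is unknown. The version of the caller and the genome build are not given in the sources used here.

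For the nucleosome libraries, the authors deposited the start and end of each aligned fragment, selected by length and unique mapping, with no signal or normalised value. Fragments ran from 123 to 258 bp. The submitters' processing notes name Bowtie2, without a version. Fragments outside this length range and in repeated sequence are missing, so neither small particles nor repeats can be described. The MNase-seq library held 8481426 fragments, the input 7409029 and the H2A.Z ChIP 7901363. Fragments with the same start and end as another made up 3.13% of the MNase-seq library, 5.70% of the input and 17.0% of the ChIP library, and were kept in the main analysis.

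Nucleosome centres (dyads) were called from the midpoints of MNase-seq fragments, smoothed with a Gaussian of SD 20 bp. Local maxima were taken from the highest down, at least 120 bp apart. Linker DNA was defined as positions more than 73 bp from the nearest dyad, among positions within 130 bp of a dyad. When linkers were counted as units, a linker was the DNA between neighbouring dyads at most 300 bp apart. H2A.Z enrichment of a nucleosome was the log2 ratio of ChIP to input fragments with midpoints within 73 bp of the dyad, each scaled by its library total, with 5 fragments added to each count, for nucleosomes with at least 20 input fragments. Nucleosomes with a log2 ratio above 0 were called enriched. The positioning score was the percentage of midpoints within 73 bp of the dyad that lay within 20 bp of it, for nucleosomes with at least 30 midpoints in the main comparison. The methylated percentage was compared at sites with a coverage of at least 20. The code was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.

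No genome sequence was at hand for the sequence names used in the files. The overlapping 41-base contexts of the calls were joined into 7238219 bases of known sequence, with 0 contradictory bases, which is 7.06% of the span covered by the libraries. This sequence gave 4844200 adenines absent from both lists. Of the quality list, 282343 calls could each be paired with 1 such adenine, followed by the same base and drawn at random from the same 2000-bp bin. These control adenines all lie within 20 bp of some call, so they share the surroundings of the calls and make the comparison a narrow one. A wider control drew uncalled adenines followed by the same base from the known sequence of any bin. It did not sample the whole genome, and its adenines also lie within 20 bp of some call. Random positions of the same bins and control adenines at least 50 bp from the quality list were added as controls after the data had been examined. The latter still lie within 20 bp of some call of lower quality, and they could be paired with 153796 calls. The definitions of the dyads, linker positions, H2A.Z log2 ratio, positioning score and first control were set before the data were examined. The written plan gave neither the cut at a log2 ratio of 0 nor the limit of 300 bp for linkers counted as units. The comparisons of linkers and nucleosomes by H2A.Z class, of spacing, of runs, of flanking bases and of whole sequences were chosen afterwards.

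Shares carry 95% Wilson intervals. Intervals of medians come from order statistics, and intervals of differences combine those of both sides. All of them cover counting error at most, because sites, linkers and nucleosomes within 1 library are not replicates. In the H2A.Z and positioning differences, sites that share a nucleosome each count its value, so those intervals are too narrow even for counting error. Dyad calling was tested on simulated fragments of evenly spaced nucleosomes, all with the same expected depth of 14 midpoints, the median of the data. The called dyads were less even in spacing and depth, so the accuracy for them may be lower. In the simulation, 100.0% of the planted dyads were placed within 20 bp when midpoints scattered with an SD of 15 bp, and 87.7% with an SD of 30 bp. A planted H2A.Z log2 difference of 2 was recovered as 1.82 because of the added fragments. Negative differences were not simulated. Unenriched nucleosomes had a median of 1 ChIP fragment, so the 5 added fragments largely set their log2 ratio, which is no measure of how far H2A.Z was depleted there. The alternatives tried were the full call list, a coverage of at least 40, an identification quality of at least 30, other smoothing and fragment lengths for the dyads, dyads from the input library, other controls, other distance limits, MNase-seq in place of the input, other added counts and scaling, and repeated fragments counted once.

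The planned share of all adenines called was not analysed here, because no genome sequence was at hand. The annotation at hand names genes on another set of sequence names, which could not be joined to those of the files. The planned results that need genes were therefore not analysed either. They were the share of m6A in genes and in their first 1 kb, the correlation with H2A.Z across genes, the profile downstream of gene starts, fixed gene lists, and genes of RNA polymerases I and III. The planned rule for named genes ranked genes by m6A per kb and H2A.Z enrichment, and named no gene for the same reason. Regions are instead given by sequence name, start and end, with no statement of what gene they lie in. The sequences and runs named were the extremes of their tables and were chosen after their values were seen.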

Results

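The data describe m6A and nucleosomes in the macronuclear genome of growing Tetrahymena. SMRT sequencing gave 283759 m6A calls in the quality list, on 461 reference sequences. The plus strand carried 141392 of these calls and the minus strand 142367. The median coverage of a called adenine was 34 reads on its strand (interquartile range 30 to 39). The median methylated percentage, the estimated share of molecules with the modification, was 86.7% (interquartile range 74.5 to 97.2). Nucleosomes were mapped by 8481426 MNase-seq fragments with a median length of 157 bp. H2A.Z was measured by 7901363 ChIP fragments and 7409029 input fragments, with median lengths of 162 and 157 bp. The libraries together covered 102.5 Mb on 970 sequences.

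The first question was in which sequence m6A occurs. Methylation lay almost entirely at adenines followed by thymine. Of the quality list, 272467 calls (96.02%, 95% interval 95.9 to 96.1) were at AT dinucleotides, against 28.03% of the 4844200 uncalled adenines in the known sequence. The dinucleotide AA, which made up 46.6% of uncalled adenines, held 0.879% of the calls. AG held 2.75% and AC 0.349%. Calls at AT also had the strongest signal. Their median methylated percentage was 87.5%, compared with 53.4% at AG, 64.8% at AC and 43.8% at AA, and their median IPD ratio was 4.37, compared with 2.47, 2.38 and 2.02.

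Not all AT dinucleotides were called equally often, and the bases on each side separated them widely. Among AT adenines of the known sequence that lay in linker DNA, 56.3% of those in GATC were in the quality list (55.5 to 57.1), 56.3% of those in CATG and 54.7% of those in CATC. The share was 19.9% for AATT, 14.1% for AATA and 4.33% for TATA (4.18 to 4.48). A cytosine preceded 22.3% of called AT adenines and 10.2% of uncalled ones, and a guanine 20.8% and 10.8%. After the thymine, an adenine followed in 16.5% of called and 35.5% of uncalled cases. The methylated percentage of called adenines did not follow this order. Its median was 80% in TATA, but 92.7% in GATA, 88.4% in AATA and 85.9% in GATC. The known sequence surrounds calls by construction, so these shares are above those of the whole genome.

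**Figure D1:**
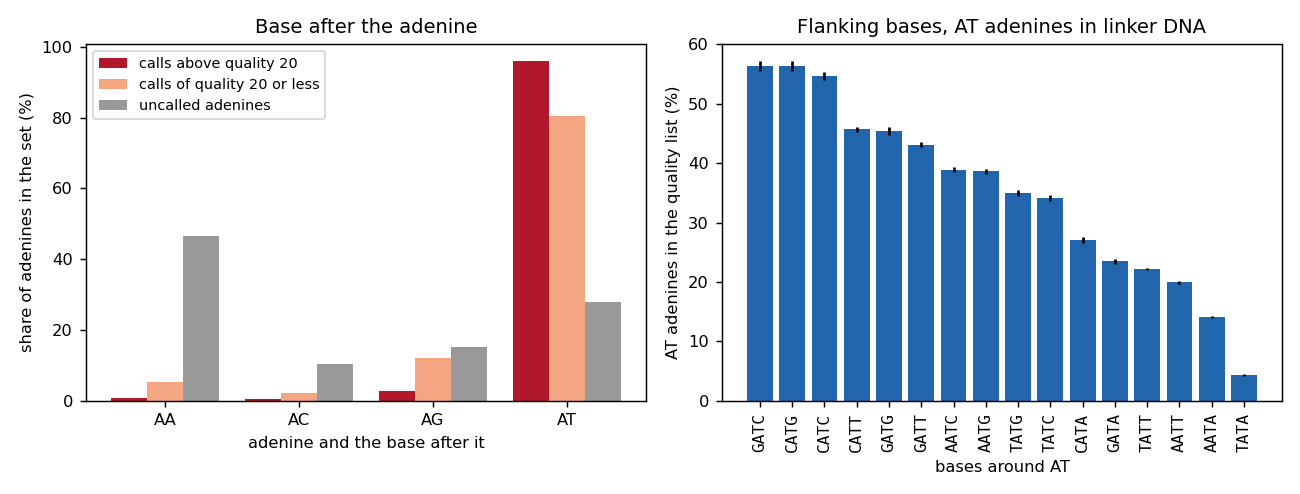
Left, the share of adenines followed by each base (%) in calls with an identification quality above 20, in calls of lower quality and in uncalled adenines of the known sequence. Right, the share of AT adenines in linker DNA found in the quality list (%) for each pair of flanking bases, with 95% Wilson intervals as error bars, which falls from 56.3% in GATC to 4.33% in TATA.

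AT reads the same on both strands, so each dinucleotide can carry m6A on 1 strand or on both. The 272467 calls fell on 199888 dinucleotides. The adenine of the opposite strand was also in the quality list for 53.3% of the calls (53.1 to 53.5), and had a call of any quality for 78.2% (78.1 to 78.4). Of all AT adenines in the known sequence, 14.9% were in the quality list, and of those in linker DNA 26.5%. For partners in linker DNA the observed share was 55.0%. Giving each partner the rate of adenines with its flanking bases and its distance to the dyad in 10-bp bins would yield 31.8%, below the 53.3% observed. That rate was not matched on region or read depth, so the gap does not isolate a link between the strands. The share called on both strands depended on depth and on the list. It was 42.2% at a coverage of up to 25 and 60.9% at a coverage above 40, and 41.7% among calls with a quality of at least 30. Requiring a coverage of at least 40 of both adenines gave 33.8%, since partners with fewer reads were then left out.

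Adenines called on both strands had a higher methylated percentage than those called on 1 strand, with medians of 89.5% (interquartile range 78.9 to 98.4) and 84.7% (72.3 to 95.9). The difference was 4.80 percentage points (4.66 to 5.02), and it was 14.2 points in the full list and 7.50 points at a coverage of at least 40. The adenines called on 1 strand include 67462 whose partner had a call of lower quality, with a median of 87.1%, and 58883 with no partner call, with a median of 81.4%. At the 72579 dinucleotides called on both strands, the percentages of the strands differed by a median of 10.5 points. That is below the median width of the caller's own interval for a single adenine, 36.7 points.

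The second question was where m6A lies relative to nucleosomes. The m6A sites avoided nucleosome cores and filled a narrow band of linker DNA. MNase-seq gave 495042 dyads with a median distance between neighbours of 197 bp (interquartile range 168 to 231) and a median of 14 midpoints each. Linker DNA held 83.3% of m6A sites (83.1 to 83.4) and 40.8% of control adenines (40.6 to 40.99), a difference of 42.5 percentage points (42.2 to 42.7). At random positions of the same bins the linker share was 27.5%, so the difference was 55.8 points. The control matched also on A+T content gave 28.2 points. Its adenines lay a median of 8 bp from the quality list, compared with 15 bp for the first control, and 54.5% of them were in linkers. Adenines of the first control with equally known surroundings, a median of 9 bp away, were in linkers in 51.6% of cases without that matching.

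Distances from the dyad gave a sharper picture of the AT sites. Of these, 64.6% lay 80 to 99 bp from a dyad, against 13.9% of random positions. Within 49 bp of a dyad lay 1.31% of the sites (3580) and 47.1% of random positions. Sites were 4.99 times as frequent as random positions at 90 to 99 bp and 0.0228 times as frequent at 0 to 9 bp. The methylated percentage followed the same course, with a median of 70.9% at 0 to 9 bp and 89.4% at 90 to 99 bp. Where neighbouring dyads were 180 to 220 bp apart, 78.7% of the 178273 AT dinucleotides lay within 20 bp of the middle of the linker. An even spread over the whole interval between the dyads, nucleosome DNA included, would put 20% there. The linker DNA of such intervals lies mostly within 20 bp of the middle, so this share does not show centring within the linker. The calls outside AT behaved otherwise. Their linker share was 28.7% (27.9 to 29.6), close to the 27.5% of random positions (27.4 to 27.7). Those positions came from the bins of the whole quality list, so a difference this small cannot be interpreted. By next base the linker share was 32.9% for AA (31.1 to 34.8), 29.9% for AC (27.04 to 32.8) and 27.3% for AG (26.3 to 28.3).

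**Figure D2:**
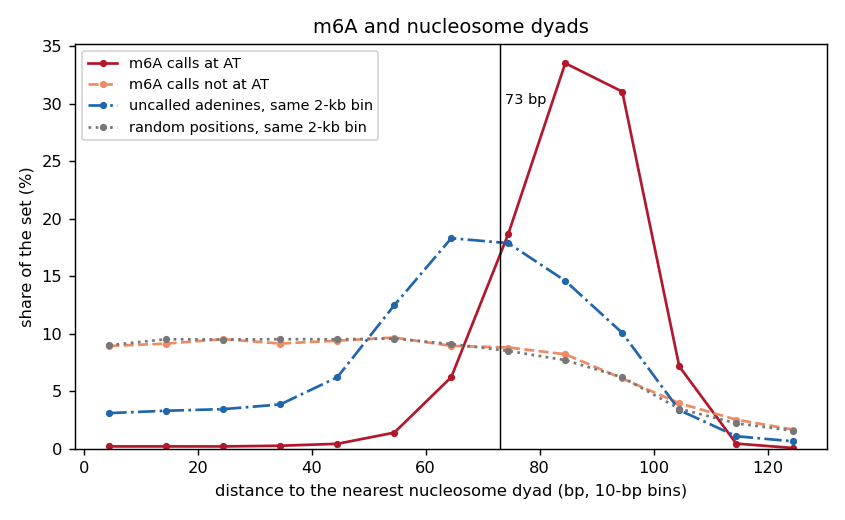
Share of each set of positions (%) by distance to the nearest nucleosome dyad in 10-bp bins, for m6A calls at AT, m6A calls not at AT, control adenines and random positions; the vertical line marks 73 bp, the limit of linker DNA. The AT calls peak between 80 and 99 bp, while calls outside AT lie close to the random positions.

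The sites were also spaced like nucleosomes. Pairs of AT dinucleotides with m6A were most frequent at short range, within a linker. Beyond the first trough, near 99 bp, their number peaked at distances of 196, 392 and 590 bp, and the period of the dyads measured in the same way was 196 bp. At the first of these peaks there were 9065 pairs per bp, and at that trough there were 25.7, a ratio of 352. The later peaks were lower, at 3446 and 749 pairs per bp.

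**Figure D3:**
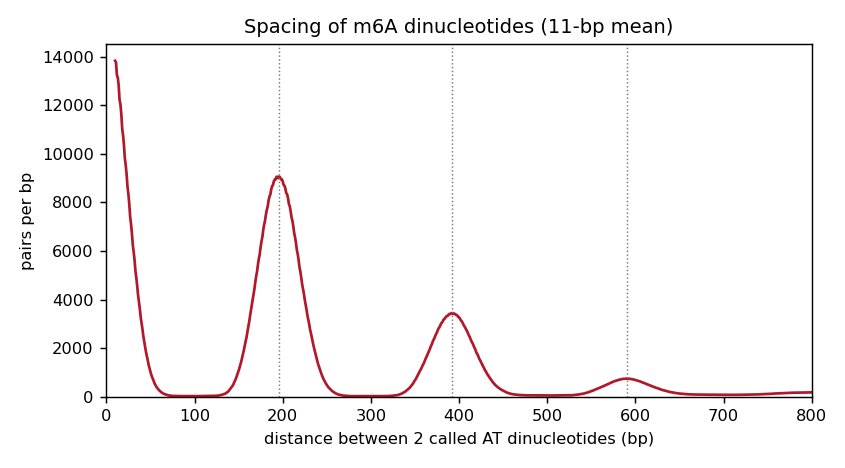
Number of pairs of AT dinucleotides with m6A (per bp, mean over 11 bp) against the distance between them (bp). The dotted lines mark the peaks at 196, 392 and 590 bp.

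Of all 464263 linkers, 52972 (11.4%) held m6A, with a median of 4 AT dinucleotides (interquartile range 2 to 5) and at most 15. Linkers with m6A came in short runs of neighbours. There were 23254 runs, of which 29.4% consisted of 1 linker, 28.3% of 2, 29.5% of 3 and 10.9% of 4. Runs of up to 4 linkers made up 98.1%. The longest held 8 linkers and were found at 2 places. The run on sequence scf_8254644, from 212155 to 213764, held 23 dinucleotides with m6A between 9 nucleosomes, all with an H2A.Z log2 ratio above 0 (median 1.85), though 8 of the 9 passed the minimum of input fragments. The run on scf_8254803, from 511878 to 513455, held 18 dinucleotides between 9 nucleosomes with a median log2 ratio of 1.95.

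**Figure D4:**
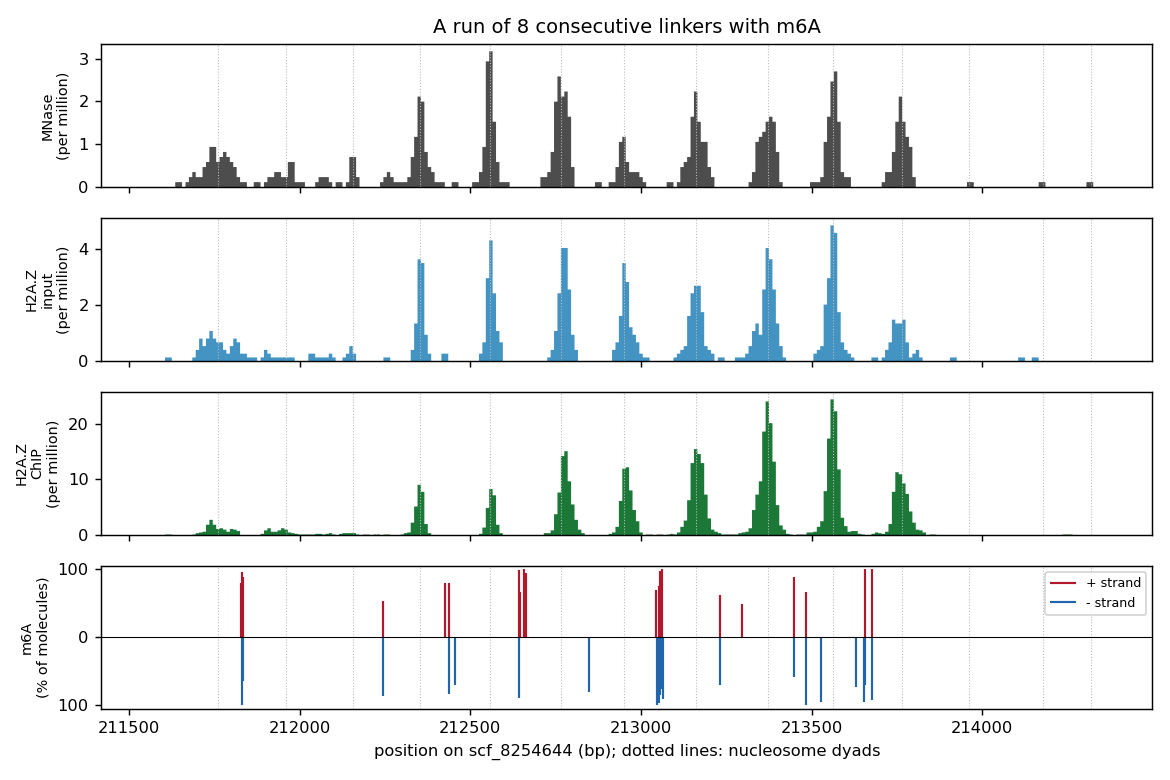
Map of the run of 8 linkers on scf_8254644, with positions in bp along the horizontal axis. The upper panels give fragment midpoints, scaled by the library total, in a sliding window for MNase-seq, input and H2A.Z ChIP, and the lowest panel gives the methylated percentage of each m6A call, upward for the plus strand and downward for the minus strand. Dotted lines are dyads called from MNase-seq, and the calls fall mostly between them.

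The third question was how m6A relates to H2A.Z. Nucleosomes fell into 2 classes. Of the 123849 nucleosomes with enough input fragments (25.02% of all dyads), 40603 (32.8%) were enriched in H2A.Z, with a median log2 ratio of 1.77. The others had a median of -2.35, a value set largely by the 5 added fragments, and 4.83% of nucleosomes lay within 0.5 of a log2 ratio of 0. An enriched nucleosome had a median of 118 ChIP and 28 input fragments, and an unenriched nucleosome 1 and 26.

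Linkers carried m6A where H2A.Z nucleosomes stood on both sides. Of 17854 linkers between 2 enriched nucleosomes, 80.2% held m6A (79.6 to 80.8), with a mean of 2.92 AT dinucleotides. With 1 enriched neighbour it was 9.89% of 4518 linkers (9.06 to 10.8). With 0 enriched neighbours it was 1.45% of 33955 linkers (1.32 to 1.58). Seen from the nucleosome, H2A.Z was enriched at 99.5% of the 14300 nucleosomes with m6A in the linkers on both sides, with a median log2 ratio of 1.93 (interquartile range 1.66 to 2.17). It was enriched at 86.5% of the 17884 with m6A on 1 side and at 6.91% of the 79404 with none. These shares depended on the calls kept and on the limit of enrichment. With calls restricted to a coverage of at least 40, linkers between 2, 1 and 0 enriched nucleosomes held m6A in 24.1%, 3.19% and 0.374% of cases, since most calls were then left out. Leaving out calls can only lower the shares, so this fall does not measure how far depth limited them. With the full list the shares were 87.2%, 19.9% and 5.60%, and with enrichment set at a log2 ratio above 1 they were 88.8%, 32.9% and 2.63%.

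The share of linkers with m6A varied with nucleosome spacing between H2A.Z nucleosomes, and was low at every spacing between unenriched ones. Between 2 enriched nucleosomes, 87.6% of linkers held m6A when the dyads were more than 190 and up to 200 bp apart. The share was 51.9% at 160 to 170 bp and 9.73% at 240 to 300 bp. Between unenriched nucleosomes it stayed between 0.930% and 1.88% over the same distances. Adenines whose nearest nucleosome was enriched had a median methylated percentage of 88.2% (n = 110028), and those beside an unenriched nucleosome 77.3% (n = 1101).

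**Figure D5:**
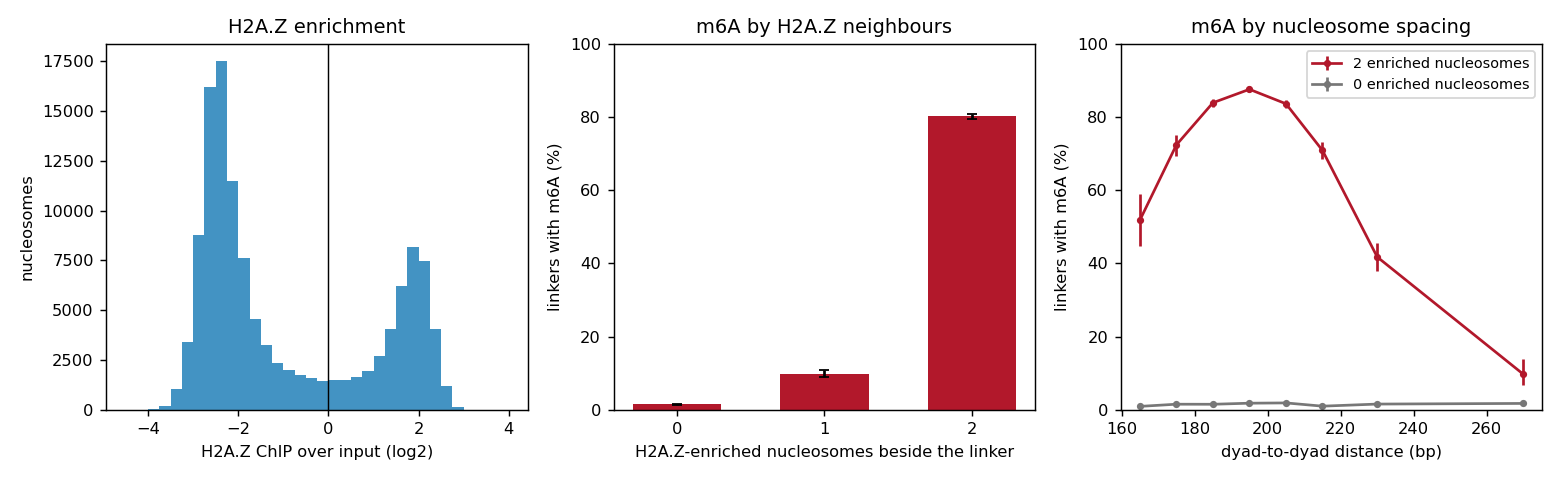
Left, number of nucleosomes by H2A.Z ChIP over input (log2), with the line at 0 parting enriched from unenriched nucleosomes. Middle, share of linkers with m6A (%) by the number of enriched neighbours, rising from 1.45% to 80.2%; right, the same share by the distance between dyads (bp) for linkers between 2 or 0 enriched nucleosomes; error bars are 95% Wilson intervals.

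Against control adenines of the same bins, nearest nucleosomes differed little in H2A.Z. The control adenine had the same nearest nucleosome as its m6A site in 24.2% of pairs, and in 79.2% its nearest nucleosome was also the nearest one of some m6A site. Each site or control adenine contributed the value of its nearest nucleosome, so a shared nucleosome counted more than once and the intervals here are too narrow. The median log2 ratio was 1.90 at the nucleosome nearest to m6A and 1.81 at that nearest to control adenines, a difference of 0.08 (0.08 to 0.09). It was 0.33 with control adenines from the known sequence of any bin, which also lie within 20 bp of some call. The difference was 0.38 against random positions of the same bins and 0.71 against control adenines at least 50 bp from the quality list. With MNase-seq as the denominator it was 0.15. The median positioning score was 78.9% beside m6A and 77.8% beside control adenines, a difference of 1.17 percentage points (0.896 to 1.47). That difference was 4.75 points with control adenines from the known sequence of any bin. It was 5.42 points against random positions and 7.36 points against controls at least 50 bp from the quality list. Those controls all lie within 20 bp of a call of lower quality, and they were paired with 153796 calls. The control matched also on A+T content gave 0.739 points. With at least 60 midpoints per nucleosome it was 0.126 points (-5.13 to 8.51), a depth at which too few nucleosomes remained to detect a difference.

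The density of m6A varied between reference sequences. Over the 382 sequences of at least 20000 bp the median was 2.31 calls per kb (interquartile range 1.24 to 3.45). The highest densities were 7.06 calls per kb on scf_8254062, which spans 50815 bp, and 7.03 on scf_8254393, which spans 52920 bp. The sequences scf_8254099, scf_8254414 and scf_8254681 had 0 calls in the quality list and 5, 17 and 16 in the full list. The median coverage of those calls was 25, 15 and 35.5 reads, compared with 34 in the quality list. Low depth may have kept some calls on scf_8254099 and scf_8254414 out of the quality list. The calls on scf_8254681 were not of low depth. The ratios of ChIP to input fragments on these sequences, scaled by library totals, were 0.0465, 0.0424 and 0.0730, whereas those of scf_8254062 and scf_8254393 were 1.75 and 1.99. The next densest sequence, scf_8254260, had 6.60 calls per kb and a ratio of 0.775. Across the 382 sequences, calls per kb and the ratio of ChIP to input went together, with a Spearman rho of 0.874 and a Pearson r of 0.858. Sequences within 1 library are not independent replicates, so these coefficients describe the sequences and carry no test.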

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

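The test of reads on the second strand and that of the base composition after calls outside AT were chosen only after the results had been seen, as were the comparisons of linkers by H2A.Z class. The other tests described here had their predictions written before their results were seen.

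A signal appeared in data that the main comparisons leave out and only the full list holds, the AT calls with an identification quality of 20 or less. Of these 194674 calls, 76.3% lay in linker DNA (76.1 to 76.5), compared with 85.5% of the AT calls in the quality list. Random positions in the bins of the quality list lay there in 27.5% of cases, and none were drawn from the bins of these calls. All 194674 together had a median coverage of 32 reads and a median methylated percentage of 68.9%. Those with no call of any quality on the opposite strand, 39.9% of them, lay in linkers in 63.7% of cases. Control adenines of the quality list are a closer baseline, and 40.8% of them lay in linkers. The share was 51.6% for those with equally known surroundings and 54.5% for those matched also on A+T content. No such control was drawn for the calls of lower quality alone.

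AT sites called on 1 strand only were compared with what false calls or thin coverage would give. Sites with no partner call of any quality lay in linkers 50.8 percentage points more often than random positions (78.3% against 27.5%). The linker share was 40.8% for control adenines of the quality list and 54.5% for those matched also on A+T content. This argues against false calls spread over such adenines as the main source. False calls that favour linkers themselves could not be told apart by this test. The share called on both strands was 60.9% at a coverage of the called adenine above 40 and 42.2% at 25 or less. With this difference of 18.8 percentage points, too few reads for the partner to enter the quality list may account for part of the sites called on 1 strand. The share with a partner of any quality rose less, from 73.8% to 80.3%, so part of the sites stayed without one. The depth at partners without a call is unknown and was not tested. No biological explanation was tested, since the design has no group that separates strands, and true methylation of a single strand remains open.

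Calls outside AT lay in linkers about as often as random positions in the bins of the whole quality list (28.7% against 27.5%). For these calls, 2 sources in the polymerase kinetics were weighed. A shadow of a nearby m6A at AT is argued against, because 4.85% of them (4.47 to 5.26) lay within 10 bp of an AT call and 3.75% of random positions did, a ratio of 1.29. An adenine stood at the fourth base after 91.1% of these calls and after 39.1% of uncalled adenines with the same next base, a difference of 52.0 percentage points, while the share was 38.8% for AT calls. Sequence-dependent polymerase speed may contribute, but this feature prompted the test, and base composition is no measure of speed. Methylation at a motif would show the same composition, so both stay open and no biological explanation was tested.

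Linkers between H2A.Z nucleosomes were compared with others under matched conditions. Among linkers between nucleosomes 180 to 210 bp apart with positioning scores of at least 70% and at least 10 midpoints each, 5.11% of 176 between unenriched nucleosomes held m6A (2.71 to 9.43) and 93.3% of 7809 between enriched ones, a ratio of 0.0548, which argues against positioning and spacing alone. Among pairs with 20 to 30 input fragments each the shares were 1.29% of 14835 and 84.5% of 5553, a ratio of 0.0153, which argues against input depth. A biological link between H2A.Z and m6A may remain as a hypothesis, and the order of events cannot be read from these data. SMRT coverage at linkers without a call is not in the files and was not tested.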

How the results depend on the processing

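The controls by random positions or at least 50 bp away, the minimum of 10 midpoints, counting repeated fragments once and all alternatives for linkers by H2A.Z class, nucleosomes with m6A on both sides and the period were chosen after the results had been seen; the others were set before. Over 11 results and 83 alternatives, 33 values stayed within the interval of the reported value and 50 moved beyond it. The interval covers counting error at most, except for the period, where a margin of 5 bp was used. The 4 signed differences kept their sign under all 43 of their alternatives, whereas the shares and the period have no sign to change. The intervals are narrow because sites are many. Where no cause is given below, the cause was not tested.

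With the full list, the AT share was 88.9%, the both-strand share 70.7%, its difference in methylated percentage 14.2 points, the linker difference 34.97 points, the linkers with m6A 87.2%, 19.9% and 5.60% for 2, 1 and 0 enriched neighbours, and the enriched share of nucleosomes with m6A on both sides 97.6%. At a coverage of at least 40 these were 94.0%, 33.8%, 7.50 points, 42.8 points, 24.1%, 3.19%, 0.374% and 99.6%, and the H2A.Z difference was 0.10; the both-strand and linker shares fell because calls with fewer reads were removed. A quality of at least 30 gave an AT share of 97.6% and a both-strand share of 41.7%.

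The linker difference was 40.4 and 42.9 points with smoothing SDs of 10 and 30 bp, and 41.4 with fragments of 130 to 170 bp. It was 41.6 with dyads from the input, 28.2 with A+T matching and 45.4 with known adenines of any bin as control. With random positions it was 55.8, with controls at least 50 bp from the quality list 50.4, and with dyads of at least 10 midpoints 40.1. Linkers from 63 bp gave 33.5 and no distance limit gave 41.6. The H2A.Z difference was 0.057 with A+T matching, 0.33 with known adenines of any bin, 0.38 with random positions and 0.71 with controls 50 bp away. It was 0.15 over MNase-seq and 0.078 with repeated fragments counted once. The positioning difference was 0.739, 4.75, 5.42 and 7.36 points under those 4 controls and 0.126 points with at least 60 midpoints, where few nucleosomes remained.

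Over MNase-seq, linkers between 2 enriched nucleosomes held m6A in 77.3% of cases and 99.2% of nucleosomes with m6A on both sides were enriched. At least 10 input fragments gave 83.4% between 2 enriched nucleosomes. With repeated fragments counted once it was 77.2% with 2 enriched neighbours and 8.13% with 1. Enrichment above a log2 ratio of 1 gave 88.8%, 32.9% and 2.63% for 2, 1 and 0 enriched neighbours and 95.9% for nucleosomes with m6A on both sides, as the unenriched class then took in weakly enriched nucleosomes by construction. The period stayed at 196 to 197 bp. Depth limits the H2A.Z classes to 25.02% of dyads. The gene-based results and their alternatives were not run, for lack of an annotation on these sequence names.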

Other observations

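The comparisons described here were all chosen after the data had been examined, and they are given as values with no test. Of the 15260 linkers with m6A whose neighbours were both measured, 93.9% (93.5 to 94.2) lay between 2 H2A.Z-enriched nucleosomes. Within that class the share with m6A followed the level of H2A.Z. When the less enriched neighbour had a log2 ratio between 0 and 0.5, 32.0% of 1606 linkers held m6A (29.8 to 34.3), with a mean of 0.753 AT dinucleotides. Between 1 and 1.5 it was 78.3% of 3625 linkers, and above 2 it was 94.2% of 3476 linkers (93.4 to 94.97), with a mean of 3.62.

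Positioning of the neighbours went with m6A as well. Among linkers between enriched nucleosomes 180 to 210 bp apart, m6A was present in 27.0% of the 89 whose less well-positioned neighbour had a score below 40% (18.8 to 37.0). The share was 61.2% of 1418 linkers at scores from 40 to 55%, 80.8% of 5028 from 55 to 70% and 93.3% of 7920 from 70% upward. No minimum of midpoints was applied here. Between unenriched nucleosomes of the same spacing the shares were 1.47%, 1.49%, 2.70% and 5.59%. Within a linker, distances between m6A dinucleotides of 5 to 28 bp, a range in which each multiple of 3 has a neighbour on either side, were multiples of 3 in 37.4% of 275078 pairs (37.3 to 37.6). The share was 34.5% of 2076950 pairs of AT dinucleotides in the known sequence, and a linear decline with distance would give 33.3%. Each of the 8 multiples exceeded both neighbouring distances among m6A pairs, and 6 of 8 did so in the known sequence.

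A pair of short sequences was read far more deeply than the rest. On scf_8254915, which spans 1402 bp, the median coverage of called adenines was 2433 reads, and on scf_8253895, which spans 999 bp, it was 880.5 reads. Their 50 calls included 7 at AT (14%, 6.95 to 26.2), with a median methylated percentage of 10.2% and a median IPD ratio of 1.35, far below the 4.30 of the quality list.

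Some sequences present in MNase-seq were almost missing from the H2A.Z experiment. Among 516 sequences of at least 5000 bp with at least 200 MNase-seq fragments, 13 sequences of 261.8 kb in all held 14068 MNase-seq fragments, 173 input fragments and 9 ChIP fragments. Their scaled ratio of input to MNase-seq was 0.0141, whereas the median of the other sequences was 0.955 and their lowest value 0.180. The longest were scf_8254662, spanning 55588 bp with 3223 MNase-seq, 18 input and 1 ChIP fragments, and scf_8254375, spanning 46126 bp with 2689, 13 and 2. Of their 127 m6A calls, 101 lay on 3 sequences (scf_8254750, scf_8254704 and scf_8254568) with 2.54 to 2.65 calls per kb, near the 2.77 per kb over all sequences. The other 10 sequences held 26 calls over 222.7 kb, 0.117 per kb. The A+T content of the contexts of their calls was 78.6%, and 75.6% for the other sequences. The labels do not say whether the input and MNase-seq libraries came from the same cells.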
